A study of Mus musculus with 24 samples.

How the data were processed

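RNA from CTCF-degron F123 mouse embryonic stem cells was sequenced on an Illumina HiSeq4000, per the labels from total RNA. Auxin was given as 1 µl of a 500 mM stock per ml of medium, which was changed every 24 h. The 24 libraries fall into 12 groups of 2: ES cells after 0, 24, 48 and 96 h of auxin, differentiating cells on days 2, 4 and 6 without and with auxin, and cells harvested 2 days after auxin was washed out on day 4 or day 6. Groups and replicate numbers were read from the sample titles, and every count column matched 1 sample.

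The authors deposited read counts per gene, as whole numbers with 1 column per library and no normalization. The labels name STAR, HTSeq, edgeR and the mm10 build of the mouse genome. Versions, annotation release and strand settings are not given in the sources used here. Counts of 51697 named genes were used, and 1 line without a gene name was left out. Among counts of 1 to 20, 59.6% to 78% of values per library were even, so dividing all counts by 2 was tried as an alternative. Reads shared between near-identical genes cannot be assigned to a single copy, which concerns the Usp17l, Zscan4, Tdpoz and protocadherin families. Coordinates come from the GENCODE vM21 annotation, on the same build, by gene symbol, for 94.8% of tested genes.

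All fits used R 4.3.3. Genes with enough counts were kept by filterByExpr of edgeR 4.0.16, with a minimum count of 10 in the smaller group and a minimum total of 15, which left 23831 genes. Libraries were scaled by the trimmed mean of M-values. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 24 libraries, and each comparison was tested as a contrast of group means. The common dispersion was 0.0439. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene counted as changed at an adjusted p below 0.05. Standard errors were derived from the log2 fold change and its F statistic. CPM values are counts per library scaled by these library sizes to a common total. Where a group had 0 counts in both libraries, the fold is a lower bound against 3 counts over the group, and it covers counting error only. With all counts halved, such a bound would be 2-fold lower.

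The 17 comparisons were auxin against 0 h in ES cells, 96 h against 24 h, each control day against ES cells, auxin against control on each day, each washout group against day 6 auxin and day 6 control cells, and 3 differences between auxin effects. Fixed gene lists, 33 in all and written with the comparisons before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Of the symbols in the lists, 92% matched the count table, and 31 lists had enough tested members. Of 527 list tests, 248 passed. With a correlation estimated from the data 57 passed, with fry 188 and with a replicate block 255. In the report, a list given with a single adjusted p passed with the correlation estimated in the fit of 24 libraries as well, unless it did not pass at all. The protocadherin alpha and mitochondrially encoded lists were not analysed here.

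Genes named in the text follow a rule fixed beforehand. It takes Ctcf, up to 8 genes with the largest changes each way among changed genes with a mean log2 CPM of at least 1 and separated libraries, and up to 4 members of each list described. Pou5f1, Nanog, Sox1, Pax6, Nes and Tubb3 are added for differentiation, and Vcan for auxin. Some genes that meet the rule are not reported here.

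Replicate numbers were checked for pairing by correlating, across genes, the replicate differences of each of 66 pairs of groups. They marked a shared shift in all 6 pairs of ES groups, at 0.18 to 0.79, while the 28 pairs of differentiation groups ran from −0.28 to 0.24. Common dispersion was 0.134 in the 8 ES libraries alone, 0.0511 with a replicate block and 0.0051 in the 16 differentiation libraries. A single fit thus overstates the precision of comparisons among ES cells and understates that of comparisons among differentiation groups. Comparisons of control days with ES cells, and differences that include an ES effect, also use ES libraries, so their precision may be overstated. Fits of each set alone were added for this reason. The pipeline was tested on simulated data with planted changes. For a 4-fold change on day 4, the fit of 24 libraries found 63% of 100 genes and called 0 of 23685 unchanged genes, and the 16 differentiation libraries alone found 81.8% of 99 and called 11 of 22385. For a 4-fold change at 96 h it found 65.3% of 98 genes with 853 of 23649 unchanged genes called under independent noise, and 52% of 100 with 35 of 23634 under noise with a replicate shift. The 8 ES libraries with a block found 18.6% of 86 and called 1 of 19959 under independent noise. With the shift they found 58.9% of 90 and called 11 of 20080. The shift drawn was the same in every ES group.

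Alternatives were an adjusted p below 0.01, a 2-fold minimum change, DESeq2 1.42.0, relative log expression scaling, no filter, a mean of at least 1 CPM, a replicate block, the compared groups alone, an estimated correlation or fry for the lists, and leaving out each library in turn. When a group is left with 1 library, that library is assumed to vary like the other groups.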

Results

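RNA sequencing measured gene expression in F123 cells, a hybrid mouse embryonic stem (ES) cell line whose CTCF protein carries an auxin-inducible degron. CTCF is a zinc-finger DNA-binding protein that holds chromatin loops in place, and auxin leads to the destruction of the tagged protein. ES cells were harvested after 0, 24, 48 and 96 h of auxin. Other cells were differentiated toward neural progenitors with or without auxin and harvested on days 2, 4 and 6. In washout samples auxin was removed on day 4 or day 6 and the cells were harvested 2 days later. The 12 groups had 2 libraries each, 24 in all. The question behind the series is how CTCF bound near promoters affects the expression of genes that depend on distant enhancers. No label says that replicates came from separate cultures, so the p-values measure the spread between these samples. No auxin-treated cells without the degron were analysed here, so effects of auxin itself are not separated from those of CTCF loss.

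Total counts per library ran from 24696374 to 72048935. The 4 ES libraries of replicate 1 held 24696374 to 29909368, the 4 of replicate 2 held 51686150 to 61681404, and the 16 differentiation libraries held 51053184 to 72048935. Of 51697 genes in the count table, 23831 had enough counts to be tested. Replicates of ES cells differed more than replicates of differentiating cells. The standard deviation of the log2 ratio between replicates was 0.583 to 0.714 in the 4 ES groups, 0.318 in the day 2 auxin group and 0.133 to 0.167 in the other 7 groups. The ES replicate numbers also marked a shared shift: in 6 of 6 pairs of ES groups, genes higher in replicate 2 of a group tended to be higher in replicate 2 of the other, with a correlation across genes of 0.18 to 0.79. For this reason each gene in a comparison among ES cells below is given with a second adjusted p, from a fit of the 8 ES libraries alone with a replicate block.

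The first principal component held 62.3% of the variance and ordered the samples by stage, from −80.8 in a 0 h ES library to 80.9 in a day 6 washout library. The second held 12.2%, with the day 2 libraries at −49.4 to −45.3 and the ES libraries at 2.26 to 39.2. On days 4 and 6 the auxin libraries lay below their controls on the first component, at 31.5 and 32.8 against 46.5 and 46.7 on day 4, and at 61.1 and 62.2 against 74.6 and 75.2 on day 6.

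**Figure D1:**
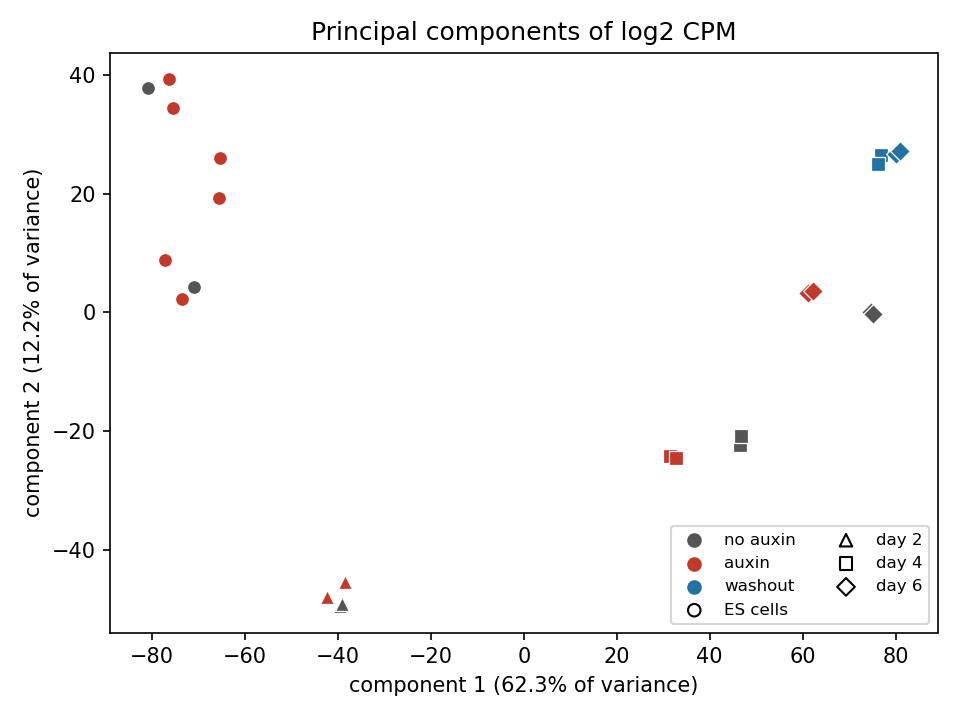
Principal components 1 and 2 of log2 CPM (scaled counts), 1 point per library (n = 24), with colour for the treatment and shape for the stage. Component 1 holds 62.3% of the variance and component 2 holds 12.2%; the day 4 and day 6 auxin libraries sit to the left of their controls.

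Ctcf (mm10 chromosome 8, 105636568 to 105682922, plus strand) mRNA was present in every library at 172 to 287 CPM (counts scaled to a common library size). The degron acts on the protein, so these values do not check its depletion. Mean Ctcf was 195 ± 31 CPM (SD, n = 2) in 0 h ES cells and 240 ± 41 after 96 h (log2 fold change 0.30 ± 0.14, adjusted p = 0.23, block adjusted p = 0.42). It was 229 ± 1.7 in day 4 controls and 282 ± 6.7 in day 4 auxin cells (log2 fold change 0.30 ± 0.14, adjusted p = 0.4), and 204 ± 0.24 and 261 ± 11 on day 6 (log2 fold change 0.35 ± 0.14, adjusted p = 0.19). Washout cells held 209 ± 6.8 after removal on day 4 and 196 ± 0.29 after removal on day 6. None of the auxin or washout comparisons passed for Ctcf in the fit of 24 libraries, but days 4 and 6 did in the 16 differentiation libraries alone (adjusted p = 0.018 and 0.0054). Below, list medians are of log2 fold changes over tested members, values after ± are standard errors of log2 fold changes, n = 2 per group, and a gene counts as changed at an adjusted p below 0.05.

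Differentiation without auxin was compared with 0 h ES cells to show which genes the protocol moves. By day 2, 2443 genes rose and 1885 fell. Retinoic acid response genes and Hox genes, which set position along the body axis, led the increases. Hoxb1 rose (log2 fold change 8.04 ± 0.50, adjusted p = 5.6e-09), as did Hoxb8 (log2 fold change 7.78 ± 0.33, adjusted p = 1.3e-10). Hoxb6 had 0 counts in ES cells and rose at least 1120-fold (adjusted p = 2.2e-08). The retinoic acid-metabolising enzymes Cyp26a1 (5.37 ± 0.26, adjusted p = 2.9e-10) and Dhrs3 (4.14 ± 0.18, adjusted p = 1.3e-10) rose, and so did Stra8 (3.88 ± 0.20, adjusted p = 3.9e-10). Among 20 tested retinoic acid response genes, 18 rose, 0 fell and 2 did not pass (18 higher and 0 lower, adjusted over the list alone). The retinoic acid median was 3.18, set test adjusted p = 2.1e-88. Of 39 Hox genes, 25 rose, 3 fell and 11 did not pass (26 higher and 4 lower, adjusted over the list alone). The Hox median was 2.94, also with members at 0 in 1 group set at their bound, set test adjusted p = 5e-58. In the naive pluripotency list, which holds genes of the early embryo-like ES state, 0 rose, 15 fell and 4 did not pass (0 higher and 16 lower, adjusted over the list alone) of 19. The naive pluripotency median was −1.14, set test adjusted p = 5.6e-26. Socs3 (−4.19 ± 0.21, adjusted p = 3.9e-10), Tdgf1 (−4.14 ± 0.24, adjusted p = 2.1e-09), Fgf4 (−2.94 ± 0.16, adjusted p = 1.3e-09) and Nanog (−1.37 ± 0.17, adjusted p = 2.2e-05) fell, as did Zfp42 (−1.59 ± 0.12, adjusted p = 7.7e-08).

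Pou5f1, a core pluripotency factor, fell on day 2 with log2 fold change −0.48 ± 0.16, adjusted p = 0.042, and adjusted p = 0.093 to 0.25 when any 1 of the 4 libraries was left out. Among neural genes Pax6 rose (2.02 ± 0.33, adjusted p = 0.00039), while Sox1 (0.58 ± 0.43, adjusted p = 0.38) and Tubb3 (0.40 ± 0.42, adjusted p = 0.55) did not pass. Chac1 (3.47 ± 0.33, adjusted p = 9.5e-07) and Trib3 (2.05 ± 0.29, adjusted p = 8e-05), targets of the integrated stress response, rose. In that list of 17, 10 rose, 0 fell and 7 did not pass (12 higher and 0 lower, adjusted over the list alone). The stress response median was 0.74, set test adjusted p = 2.9e-08 and adjusted p = 0.084 with an estimated correlation. The day 2 count of 4328 genes was 1935 without replicate 1 of the day 2 control and 1932 without replicate 2.

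By day 4, 4733 genes were higher and 4429 lower than in ES cells, and by day 6 5240 and 5185. The neural progenitor transcription factor Olig2 rose on day 4 (log2 fold change 5.39 ± 0.38, adjusted p = 5.9e-09), as did Pax6 (3.66 ± 0.35, adjusted p = 2.5e-07), Nkx6-1 (4.50 ± 0.45, adjusted p = 3.6e-07), Irx3 (4.45 ± 0.31, adjusted p = 5.5e-09) and the intermediate filament gene Nes (1.38 ± 0.21, adjusted p = 3.9e-05). Nepn and Osr1, at 0 counts in ES cells, rose at least 2180-fold and at least 614-fold. Rarb rose (6.87 ± 0.28, adjusted p = 7.8e-12). Of 34 neural progenitor genes, 24 rose, 1 fell and 9 did not pass (25 higher and 1 lower, adjusted over the list alone) on day 4. The neural progenitor median was 2.48, set test adjusted p = 1.6e-14. Fgf4 (−6.21 ± 0.19, adjusted p = 8.2e-13), Nanog (−4.18 ± 0.19, adjusted p = 3.2e-11), Pou5f1 (−1.96 ± 0.16, adjusted p = 4.6e-08) and Sox2 (−1.94 ± 0.13, adjusted p = 3.2e-09) fell. Of 17 core pluripotency genes, 2 rose, 13 fell and 2 did not pass (2 higher and 14 lower, adjusted over the list alone). The core pluripotency median was −1.94, set test adjusted p = 3.5e-16. Endoderm genes moved as well: Ttr (5.75 ± 0.39, adjusted p = 3.7e-09), Afp (6.06 ± 0.50, adjusted p = 3.5e-08) and Foxa2 (3.04 ± 0.22, adjusted p = 7.8e-09) rose, and of 22 members 17 rose, 1 fell and 4 did not pass (18 higher and 1 lower, adjusted over the list alone). The endoderm median was 1.17, set test adjusted p = 1.3e-09.

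On day 6, neuronal genes were higher as well. Dcx, a microtubule protein of young neurons, had 0 counts in ES cells and rose at least 1290-fold (adjusted p = 2.7e-10). The cell adhesion gene Cntn2 (3.07 ± 0.24, adjusted p = 1.2e-08), the transcription factors Isl1 (3.91 ± 0.27, adjusted p = 3.4e-09) and Onecut2 (4.49 ± 0.37, adjusted p = 2.9e-08), and Nes (2.66 ± 0.21, adjusted p = 2e-08) rose. Of 30 neuronal genes, 21 rose, 1 fell and 8 did not pass (21 higher and 1 lower, adjusted over the list alone). The neuronal median was 3.13, also with members at 0 in 1 group set at their bound, set test adjusted p = 6e-12. On day 4, 12 rose, 8 fell and 10 did not pass (12 higher and 8 lower, adjusted over the list alone) in this list, whose median was 0.60, also with members at 0 in 1 group set at their bound, set test adjusted p = 0.055 and adjusted p = 0.56 with an estimated correlation. Of 19 fibroblast or feeder genes, 11 rose, 5 fell and 3 did not pass (12 higher and 6 lower, adjusted over the list alone). The fibroblast median was 2.89, set test adjusted p = 0.0026 and adjusted p = 0.16 with an estimated correlation. Lum (8.64 ± 0.77, adjusted p = 1.1e-07) and Col3a1 (7.94 ± 0.81, adjusted p = 3.8e-07) rose. T, which marks early mesoderm, fell (−7.59 ± 0.76, adjusted p = 2.9e-07), as did Nanog (−5.01 ± 0.20, adjusted p = 4.7e-12), Zfp42 (−3.05 ± 0.13, adjusted p = 1.2e-11) and Pou5f1 (−2.74 ± 0.17, adjusted p = 6.5e-10). Of 20 protocadherin beta genes, 15 rose, 0 fell and 5 did not pass (17 higher and 0 lower, adjusted over the list alone). The protocadherin beta median was 4.14, or 3.46 with members at 0 in 1 group set at their bound, set test adjusted p = 1.3e-05 and adjusted p = 0.06 with an estimated correlation.

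**Figure D2:**
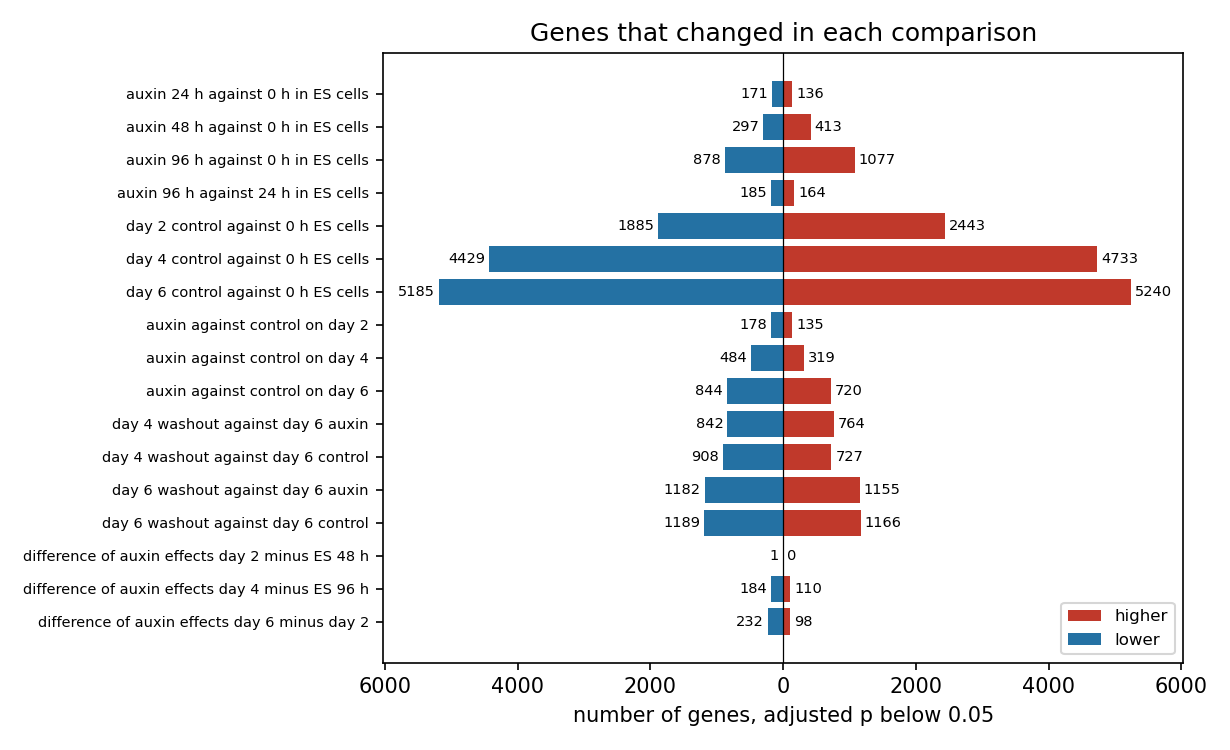
Number of genes higher (right of 0) and lower (left of 0) at an adjusted p below 0.05 in each of the 17 comparisons, out of 23831 tested. In this fit of 24 libraries auxin moved 313 genes on day 2, 803 on day 4 and 1564 on day 6, against 4328 to 10425 from ES cells to the controls of those days; with the compared groups alone these were 882, 7864 and 8976 against 238, 4419 and 5945.

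In ES cells, 24 h of auxin raised 136 genes and lowered 171. The serine protease gene Prss41 was at 0.417 and 0.238 CPM against 8.17 and 8.87 at 0 h and fell (log2 fold change −4.79 ± 0.41, adjusted p = 4.2e-06), with adjusted p = 0.024 in the 8 ES libraries with a replicate block. Dennd6b (−4.17 ± 0.63, adjusted p = 0.0014, block adjusted p = 0.014) and the cilium gene Cc2d2a (−3.08 ± 0.27, adjusted p = 7e-06, block adjusted p = 0.028) also fell. Plekhg4 (2.00 ± 0.21, adjusted p = 2.3e-05, block adjusted p = 0.031) rose. Entpd1 (3.32 ± 0.38, adjusted p = 1e-04, block adjusted p = 0.061), the collagen gene Col14a1 (3.07 ± 0.40, adjusted p = 0.00036, block adjusted p = 0.11) and the Wnt antagonist gene Nkd2 (−3.29 ± 0.40, adjusted p = 0.00017, block adjusted p = 0.1) passed without the block and not with it. Vcan, which encodes the matrix proteoglycan versican and was named beforehand because its promoter is known for a CTCF site, did not pass (log2 fold change −0.59 ± 0.36, adjusted p = 0.72, block adjusted p = 0.92, with log2 fold change 0.29 without replicate 1 of the 0 h cells). Protocadherin gamma genes, which encode adhesion proteins of the neuron surface, fell: of 21 genes, 0 rose, 12 fell and 9 did not pass (0 higher and 17 lower, adjusted over the list alone). The protocadherin gamma median was −2.89, also with members at 0 in 1 group set at their bound, set test adjusted p = 1.4e-37. With the block this call held at the preset correlation and had adjusted p = 0.26 with an estimated one. Pcdhga1 (−3.80 ± 0.54, adjusted p = 0.00076, block adjusted p = 0.028) and Pcdhga9 (−4.62 ± 0.66, adjusted p = 0.00076, block adjusted p = 0.16) fell. In the protocadherin beta cluster 0 rose, 2 fell and 18 did not pass (0 higher and 6 lower, adjusted over the list alone) of 20. The protocadherin beta median was −2.86, or −1.89 with members at 0 in 1 group set at their bound, set test adjusted p = 1.1e-07 and adjusted p = 0.056 with an estimated correlation. This call was lost with adjusted p = 0.05 without replicate 2 of the 24 h cells and with the block (adjusted p = 0.69).

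The 24 h count was less firm than these genes. The fit of 24 libraries called 307 genes, 1220 without replicate 2 of the 0 h cells, and the 8 ES libraries called 23 with a replicate block and 0 without it. In simulated ES groups with no change at 24 h, the fit of 24 libraries called 632 to 838 genes under independent noise and 1 to 5 under noise with the measured replicate shift.

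After 48 h, 413 genes were higher and 297 lower. Prss41 (−4.95 ± 0.41, adjusted p = 3.4e-06, block adjusted p = 0.024), the phosphatase gene Mdp1 (−2.57 ± 0.20, adjusted p = 2e-06, block adjusted p = 0.026), Dennd6b (−3.40 ± 0.60, adjusted p = 0.0036, block adjusted p = 0.024) and Cc2d2a (−2.57 ± 0.26, adjusted p = 3.1e-05, block adjusted p = 0.038) were lower. Col14a1 (3.86 ± 0.40, adjusted p = 3.3e-05, block adjusted p = 0.05) was higher. C2cd4a, which encodes a nuclear calcium-domain protein, was higher with 3.38 ± 0.49, adjusted p = 0.00083, but not with the block (adjusted p = 0.093). Cyp1a1, a target of the aryl hydrocarbon receptor, rose from near 0 (log2 fold change 6.43 ± 1.51, adjusted p = 0.025, block adjusted p = 0.02), with adjusted p = 0.15 without replicate 2 of the 0 h cells and adjusted p = 0.25 without replicate 1 of the 48 h cells. Genes of the 2-cell-like state, which resembles the early embryo and includes many near-identical copies, rose: of 21 members, 16 rose, 0 fell and 5 did not pass (20 higher and 0 lower, adjusted over the list alone). The 2-cell-like median was 1.41, also with members at 0 in 1 group set at their bound, set test adjusted p = 8e-26. Its members Usp17la (1.41 ± 0.24, adjusted p = 0.0028, block adjusted p = 0.092), Sp110 (1.85 ± 0.32, adjusted p = 0.0031, block adjusted p = 0.08) and Tdpoz4 (1.99 ± 0.36, adjusted p = 0.0039, block adjusted p = 0.087) passed singly without the block, and the list held with it at the preset correlation (adjusted p = 3.8e-25) but not with an estimated one (adjusted p = 0.43). Of 21 protocadherin gamma genes, 0 rose, 9 fell and 12 did not pass (0 higher and 14 lower, adjusted over the list alone). Their median was −1.98, or −1.94 with members at 0 in 1 group set at their bound, set test adjusted p = 6e-19 and adjusted p = 0.11 with an estimated correlation. Of 21 cholesterol synthesis genes, 0 rose, 6 fell and 15 did not pass (0 higher and 7 lower, adjusted over the list alone). The cholesterol synthesis median was −0.55, set test adjusted p = 5.7e-12 and adjusted p = 0.11 with an estimated correlation. The enzyme gene Msmo1 (−0.86 ± 0.14, adjusted p = 0.0016, block adjusted p = 0.092) was lower. The count of 710 genes was 1656 without replicate 1 of the 0 h cells and 453 without replicate 1 of the 48 h cells. The 8 ES libraries called 40 with a replicate block, and simulated groups with no change gave 662 to 758 calls under independent noise and 0 to 15 with the replicate shift.

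After 96 h, 1077 genes were higher and 878 lower, and 621 passed in the 8 ES libraries with a replicate block, 556 of them among the 1955 of all libraries. Prss41 (−4.73 ± 0.40, adjusted p = 3.6e-06, block adjusted p = 0.012), the Wnt effector gene Lef1 (−4.87 ± 0.96, adjusted p = 0.0038, block adjusted p = 0.019), the sialyltransferase gene St8sia3 (−4.54 ± 0.53, adjusted p = 5.7e-05, block adjusted p = 0.031), Gulp1 (−3.29 ± 0.56, adjusted p = 0.0014, block adjusted p = 0.019), Nkd2 (−3.29 ± 0.40, adjusted p = 7.8e-05, block adjusted p = 0.027) and the early mesoderm gene T (−3.11 ± 0.57, adjusted p = 0.0025, block adjusted p = 0.011) fell. Gli1, an effector of hedgehog signalling, fell (−1.93 ± 0.20, adjusted p = 2.8e-05, block adjusted p = 0.024). Havcr1 (3.16 ± 0.36, adjusted p = 5.7e-05, block adjusted p = 0.011), Cpa1 (3.24 ± 0.47, adjusted p = 4e-04, block adjusted p = 0.018), Aldh1a3 (3.21 ± 0.57, adjusted p = 0.0019, block adjusted p = 0.024) and C2cd4a (3.74 ± 0.49, adjusted p = 0.00017, block adjusted p = 0.032) rose. Cyp1a1 rose (6.80 ± 1.53, adjusted p = 0.0097, block adjusted p = 0.0057), with adjusted p = 0.07 without replicate 2 of the 0 h cells and adjusted p = 0.091 without replicate 1 of the 96 h cells. Vcan fell (−1.42 ± 0.37, adjusted p = 0.023, block adjusted p = 0.093), with adjusted p = 0.3 without replicate 1 of the 0 h cells and adjusted p = 0.13 without replicate 1 of the 96 h cells. Simulated groups with no change gave 662 to 726 calls under independent noise and 1 to 9 with the replicate shift, and the 8 ES libraries called 0 genes without a block, against 3000 by DESeq2 on all libraries.

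At 96 h, 19 of 31 lists passed the set test, and 0 with an estimated correlation. Of 21 cholesterol synthesis genes, 0 rose, 9 fell and 12 did not pass (0 higher and 14 lower, adjusted over the list alone). The cholesterol synthesis median was −0.82, set test adjusted p = 1.5e-15 and adjusted p = 0.11 with an estimated correlation. Msmo1 (−1.07 ± 0.14, adjusted p = 0.00015, block adjusted p = 0.024) and Dhcr7 (−1.19 ± 0.18, adjusted p = 0.00056, block adjusted p = 0.046) fell. Of 22 DNA replication genes, 0 rose, 10 fell and 12 did not pass (0 higher and 17 lower, adjusted over the list alone). The DNA replication median was −0.53, set test adjusted p = 2.5e-11 and adjusted p = 0.2 with an estimated correlation. Ccne1 (−0.94 ± 0.17, adjusted p = 0.0022, block adjusted p = 0.022) and Mcm3 (−0.57 ± 0.11, adjusted p = 0.0027, block adjusted p = 0.049) fell. Of 21 glycolysis and hypoxia genes, 0 rose, 10 fell and 11 did not pass (0 higher and 17 lower, adjusted over the list alone). The glycolysis median was −1.16, set test adjusted p = 1.8e-09 and adjusted p = 0.22 with an estimated correlation. This call was lost with adjusted p = 0.49 without replicate 2 of the 0 h cells. Among 17 core pluripotency genes, 0 rose, 7 fell and 10 did not pass (0 higher and 10 lower, adjusted over the list alone). The core pluripotency median was −0.66, set test adjusted p = 1.3e-07 and adjusted p = 0.2 with an estimated correlation. Of 19 naive pluripotency genes, 2 rose, 1 fell and 16 did not pass (2 higher and 1 lower, adjusted over the list alone). Their median was −0.15, set test adjusted p = 0.99 and adjusted p = 1 with an estimated correlation. In the primed epiblast list 0 rose, 5 fell and 8 did not pass (0 higher and 8 lower, adjusted over the list alone) of 13. The primed epiblast median was −1.04, set test adjusted p = 1.3e-07 and adjusted p = 0.18 with an estimated correlation. Lefty2 (−1.45 ± 0.25, adjusted p = 0.0013, block adjusted p = 0.022) and Etv4 (−1.04 ± 0.17, adjusted p = 0.001, block adjusted p = 0.024) fell. Of 19 germline genes, 8 rose, 0 fell and 11 did not pass (10 higher and 0 lower, adjusted over the list alone). The germline median was 0.60, set test adjusted p = 1.3e-07 and adjusted p = 0.18 with an estimated correlation. Tex101 (2.61 ± 0.44, adjusted p = 0.0013, block adjusted p = 0.035), Tuba3a (1.59 ± 0.27, adjusted p = 0.0013, block adjusted p = 0.033) and Sycp1 (1.03 ± 0.19, adjusted p = 0.0022, block adjusted p = 0.028) rose. Of 21 protocadherin gamma genes, 0 rose, 10 fell and 11 did not pass (0 higher and 17 lower, adjusted over the list alone). The protocadherin gamma median was −2.20, set test adjusted p = 1.3e-14 and adjusted p = 0.18 with an estimated correlation. Pcdhga1 (−3.52 ± 0.52, adjusted p = 0.00046, block adjusted p = 0.015) fell.

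Set directly against 24 h, cells at 96 h had 164 genes higher and 185 lower. Lefty2, a Nodal antagonist, was lower (−1.73 ± 0.25, adjusted p = 0.0029, block adjusted p = 0.092). Havcr1 was higher (1.91 ± 0.34, adjusted p = 0.011, block adjusted p = 0.13). The Nodal co-receptor gene Tdgf1 was lower with and without the block (−1.21 ± 0.21, adjusted p = 0.011, block adjusted p = 0.037), with adjusted p = 0.11 without replicate 2 of the 24 h cells. Of 21 cholesterol synthesis genes, 0 rose, 6 fell and 15 did not pass (0 higher and 12 lower, adjusted over the list alone). The cholesterol synthesis median was −0.61, set test adjusted p = 1.4e-17 and adjusted p = 0.058 with an estimated correlation. Of 21 glycolysis and hypoxia genes, 0 rose, 3 fell and 18 did not pass (0 higher and 16 lower, adjusted over the list alone). Their median was −1.22, set test adjusted p = 1.4e-17 and adjusted p = 0.18 with an estimated correlation. The count of 349 was 635 and 53 without replicates 1 and 2 of the 24 h cells, 559 and 640 without replicates 1 and 2 of the 96 h cells, and 3 in the 8 ES libraries with a replicate block.

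Auxin was then compared with control on each day of differentiation, to ask which genes CTCF loss moves as neural cells form. On day 2, 135 genes rose and 178 fell. Prss41 fell (log2 fold change −5.04 ± 0.41, adjusted p = 1.7e-06), as did the Wnt antagonist gene Nkd2 (−3.71 ± 0.39, adjusted p = 3.2e-05), Slc35f1 (−3.52 ± 0.35, adjusted p = 2.2e-05), Cc2d2a (−2.84 ± 0.26, adjusted p = 6.9e-06) and Gli1 (−1.99 ± 0.20, adjusted p = 2.2e-05). The retinaldehyde dehydrogenase gene Aldh1a2 rose (2.68 ± 0.26, adjusted p = 2.2e-05), as did Isx (3.61 ± 0.44, adjusted p = 0.00015), Col14a1 (2.84 ± 0.35, adjusted p = 0.00016), Foxf2 (2.27 ± 0.31, adjusted p = 0.00044), the neural progenitor gene Nkx6-1 (2.31 ± 0.44, adjusted p = 0.0089, but adjusted p = 0.067 to 0.18 in 3 of the 4 fits that left out 1 library) and Hoxc9 (1.98 ± 0.21, adjusted p = 3.7e-05). Nanog (−0.68 ± 0.17, adjusted p = 0.054), Pou5f1 (−0.12 ± 0.16, adjusted p = 0.95), Sox1 (−1.01 ± 0.43, adjusted p = 0.43), Pax6 (−0.78 ± 0.32, adjusted p = 0.38), Nes (0.78 ± 0.20, adjusted p = 0.07) and Tubb3 (−0.42 ± 0.41, adjusted p = 0.9) did not pass. In the 16 differentiation libraries alone Nanog, Sox1, Pax6 and Tubb3 were lower and Nes higher (adjusted p = 6e-07, 4.8e-05, 8e-06, 0.0031 and 2.3e-06). Of 21 protocadherin gamma genes, 0 rose, 8 fell and 13 did not pass (0 higher and 15 lower, adjusted over the list alone). The protocadherin gamma median was −1.96, set test adjusted p = 2.9e-25. Of 20 protocadherin beta genes, 0 rose, 2 fell and 18 did not pass (0 higher and 10 lower, adjusted over the list alone). The protocadherin beta median was −2.98, or −1.84 with members at 0 in 1 group set at their bound, set test adjusted p = 4.9e-14. Of 17 stress-response genes, 0 rose, 2 fell and 15 did not pass (0 higher and 8 lower, adjusted over the list alone). The stress response median was −0.63, set test adjusted p = 1.2e-09 and adjusted p = 0.056 with an estimated correlation. Among Hox genes 4 rose, 1 fell and 34 did not pass (8 higher and 2 lower, adjusted over the list alone) of 39. The Hox median was 0.34, also with members at 0 in 1 group set at their bound, set test adjusted p = 0.001 and adjusted p = 0.43 with an estimated correlation. The count of 313 fell to 105 and 106 without replicates 1 and 2 of the control and to 107 without replicate 1 of the auxin cells. The 16 differentiation libraries alone, whose replicates differed less, called 4126, of which 53.9% were higher against 43.1% of the 313.

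On day 4, 319 genes were higher and 484 lower with auxin. Neural progenitor genes fell. Olig2 (mm10 chromosome 16, 91225457 to 91228677) was at 0.147 and 0.243 CPM against 6.46 and 7.21 in controls (log2 fold change −5.10 ± 0.36, adjusted p = 2.1e-07). The transcription factor genes Rfx4 (−3.91 ± 0.36, adjusted p = 5.1e-06), Pou3f2 (−3.55 ± 0.34, adjusted p = 6.3e-06), Nkx6-1 (−3.43 ± 0.41, adjusted p = 6.2e-05) and Pax6 (−2.17 ± 0.32, adjusted p = 0.00049) fell, as did the growth factor gene Ptn (−2.16 ± 0.20, adjusted p = 6.1e-06). Of 34 neural progenitor genes, 0 rose, 16 fell and 18 did not pass (0 higher and 22 lower, adjusted over the list alone). The neural progenitor median was −1.22, set test adjusted p = 2.7e-36. Sox1 fell (−2.52 ± 0.45, adjusted p = 0.0027), with adjusted p = 0.06 without replicate 1 of the day 4 auxin cells and adjusted p = 0.056 without replicate 2 of the day 4 auxin cells, and Nes did not pass (0.31 ± 0.20, adjusted p = 0.64, or 0.0072 in the 16 differentiation libraries alone). Neuronal genes were lower already: Dcx (−3.31 ± 0.37, adjusted p = 6.4e-05), Elavl4 (−2.47 ± 0.40, adjusted p = 0.00094) and Cntn2 (−1.98 ± 0.23, adjusted p = 5.5e-05) fell, and Neurod4, at 0 counts with auxin, fell by at least 148-fold (adjusted p = 9e-05). Of 30 neuronal genes, 1 rose, 12 fell and 17 did not pass (2 higher and 16 lower, adjusted over the list alone). The neuronal median was −1.20, also with members at 0 in 1 group set at their bound, set test adjusted p = 9.7e-22. Tubb3 passed with all libraries (−1.85 ± 0.44, adjusted p = 0.023) and had adjusted p = 0.1 to 0.25 when any 1 of the 4 libraries was left out.

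Other genes with large falls on day 4 were Prss41 (−4.14 ± 0.39, adjusted p = 6.3e-06), Bak1, a gene of the cell-death machinery (−3.65 ± 0.29, adjusted p = 9.3e-07), Fgf15 (−4.04 ± 0.64, adjusted p = 9e-04), Bmp5 (−3.61 ± 0.45, adjusted p = 4e-04) and Osr1 (−3.89 ± 0.24, adjusted p = 1.6e-07). Osr1 was at 1.63 and 1.7 CPM against 26.8 and 22.8. Vcan (mm10 chromosome 13, 89655312 to 89742509) fell on day 4, at 11.8 and 10.9 CPM against 82.4 and 86.5 (−2.89 ± 0.39, adjusted p = 0.00017). Cpa1 (3.34 ± 0.44, adjusted p = 0.00015), the proton pump gene Atp4a (3.23 ± 0.30, adjusted p = 5.6e-06), Slc25a48 (2.81 ± 0.38, adjusted p = 0.00019) and Zcwpw2 (2.76 ± 0.46, adjusted p = 0.0013) rose. Gli1 fell (−3.38 ± 0.21, adjusted p = 1.2e-07), and of 13 hedgehog pathway genes, 0 rose, 4 fell and 9 did not pass (1 higher and 8 lower, adjusted over the list alone). The hedgehog median was −0.93, set test adjusted p = 1.4e-15. The retinoic acid genes Nr2f1 (−2.22 ± 0.24, adjusted p = 2.8e-05) and Crabp2 (−1.25 ± 0.17, adjusted p = 0.00023) fell, and in that list 2 rose, 5 fell and 13 did not pass (2 higher and 7 lower, adjusted over the list alone) of 20. The retinoic acid median was −0.33, set test adjusted p = 1.7e-05.

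Protocadherins remained lower on day 4. Pcdhb22 (−5.27 ± 0.64, adjusted p = 8.4e-05) and Pcdhga5 (−4.81 ± 0.59, adjusted p = 8.4e-05) fell, and Pcdhb6, at 0 counts with auxin, fell by at least 38.3-fold. Of 20 beta genes, 0 rose, 6 fell and 14 did not pass (0 higher and 14 lower, adjusted over the list alone). The protocadherin beta median was −2.94, or −2.32 with members at 0 in 1 group set at their bound, set test adjusted p = 1.5e-19. Of 21 gamma genes, 0 rose, 13 fell and 8 did not pass (0 higher and 17 lower, adjusted over the list alone). The protocadherin gamma median was −2.28, set test adjusted p = 1.1e-28. Naive pluripotency genes were higher than in controls: Fbxo15 rose (1.24 ± 0.12, adjusted p = 7.6e-06), and of 19 members, 6 rose, 0 fell and 13 did not pass (10 higher and 1 lower, adjusted over the list alone). The naive pluripotency median was 0.61, set test adjusted p = 3.7e-10. Nanog (0.70 ± 0.17, adjusted p = 0.024) and Pou5f1 (0.63 ± 0.16, adjusted p = 0.031) passed with all libraries, but Nanog had adjusted p = 0.14 to 0.23 when any 1 of the 4 libraries was left out and Pou5f1 adjusted p = 0.18 to 0.26 when any 1 of the 4 libraries was left out. Of 19 germline genes, 6 rose, 0 fell and 13 did not pass (11 higher and 0 lower, adjusted over the list alone). The germline median was 0.71, set test adjusted p = 1.2e-10. The count of 803 was 319 and 325 without replicates 1 and 2 of the control and 290 and 311 without replicates 1 and 2 of the auxin cells. The 16 differentiation libraries alone called 5318, of which 50% were higher against 39.7% of the 803.

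On day 6, 720 genes were higher and 844 lower with auxin. Neuronal genes fell. Cntn2 was at 3.87 and 3.86 CPM against 74.3 and 77.3 in controls (log2 fold change −4.29 ± 0.25, adjusted p = 4.2e-08). Elavl4 (−5.15 ± 0.42, adjusted p = 1.3e-06), Dcx (−4.54 ± 0.35, adjusted p = 1.4e-06), the growth-cone gene Gap43 (−4.13 ± 0.51, adjusted p = 4.8e-05), Stmn2 (−3.42 ± 0.34, adjusted p = 7.2e-06) and Tubb3 (−3.60 ± 0.46, adjusted p = 7.1e-05) fell, as did the long noncoding RNA Miat (−4.60 ± 0.41, adjusted p = 2.9e-06). Of 30 neuronal genes, 0 rose, 25 fell and 5 did not pass (0 higher and 27 lower, adjusted over the list alone). The neuronal median was −2.69, set test adjusted p = 1.2e-71. Olig2 (−6.44 ± 0.40, adjusted p = 6.5e-08), Rfx4 (−5.55 ± 0.39, adjusted p = 3.9e-07), Nkx6-1 (−3.50 ± 0.41, adjusted p = 2.9e-05) and Sox1 (−2.59 ± 0.46, adjusted p = 0.0014) were lower too, while Nes did not pass (−0.23 ± 0.20, adjusted p = 0.69, or 0.021 in the 16 differentiation libraries alone). Of 34 neural progenitor genes, 0 rose, 17 fell and 17 did not pass (2 higher and 18 lower, adjusted over the list alone). The neural progenitor median was −1.22, set test adjusted p = 1.2e-24. Dll1 (−2.63 ± 0.50, adjusted p = 0.0025) and Mfng (−2.42 ± 0.40, adjusted p = 0.00077), genes of Notch signalling, fell, and of 16 members, 1 rose, 5 fell and 10 did not pass (2 higher and 8 lower, adjusted over the list alone). The Notch median was −1.16, set test adjusted p = 0.00011. Vcan remained lower (−2.05 ± 0.37, adjusted p = 0.0016).

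Naive pluripotency genes were above control on day 6 as well: Zfp42 (0.97 ± 0.12, adjusted p = 6e-05), Esrrb (1.82 ± 0.24, adjusted p = 8.3e-05), Dppa3 (1.85 ± 0.24, adjusted p = 8.6e-05) and Fbxo15 (1.61 ± 0.12, adjusted p = 4.7e-07) rose, as did Pou5f1 (1.06 ± 0.16, adjusted p = 0.00032) and Nanog (0.91 ± 0.17, adjusted p = 0.0023). Of 19 members, 13 rose, 0 fell and 6 did not pass (14 higher and 0 lower, adjusted over the list alone). The naive pluripotency median was 1.02, set test adjusted p = 9.9e-18. The heart troponin gene Tnni3 (2.85 ± 0.32, adjusted p = 2.2e-05), the blood transcription factor gene Spi1 (3.81 ± 0.49, adjusted p = 7.1e-05) and Slc25a48 (3.92 ± 0.40, adjusted p = 8.4e-06) were among the genes with the largest rises. Of 20 protocadherin beta genes, 0 rose, 11 fell and 9 did not pass (0 higher and 16 lower, adjusted over the list alone). The protocadherin beta median was −2.76, also with members at 0 in 1 group set at their bound, set test adjusted p = 5.5e-20. The count of 1564 was 723 and 713 without replicates 1 and 2 of the control and 686 and 682 without replicates 1 and 2 of the auxin cells, and 6588 in the 16 differentiation libraries alone.

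**Figure D3:**
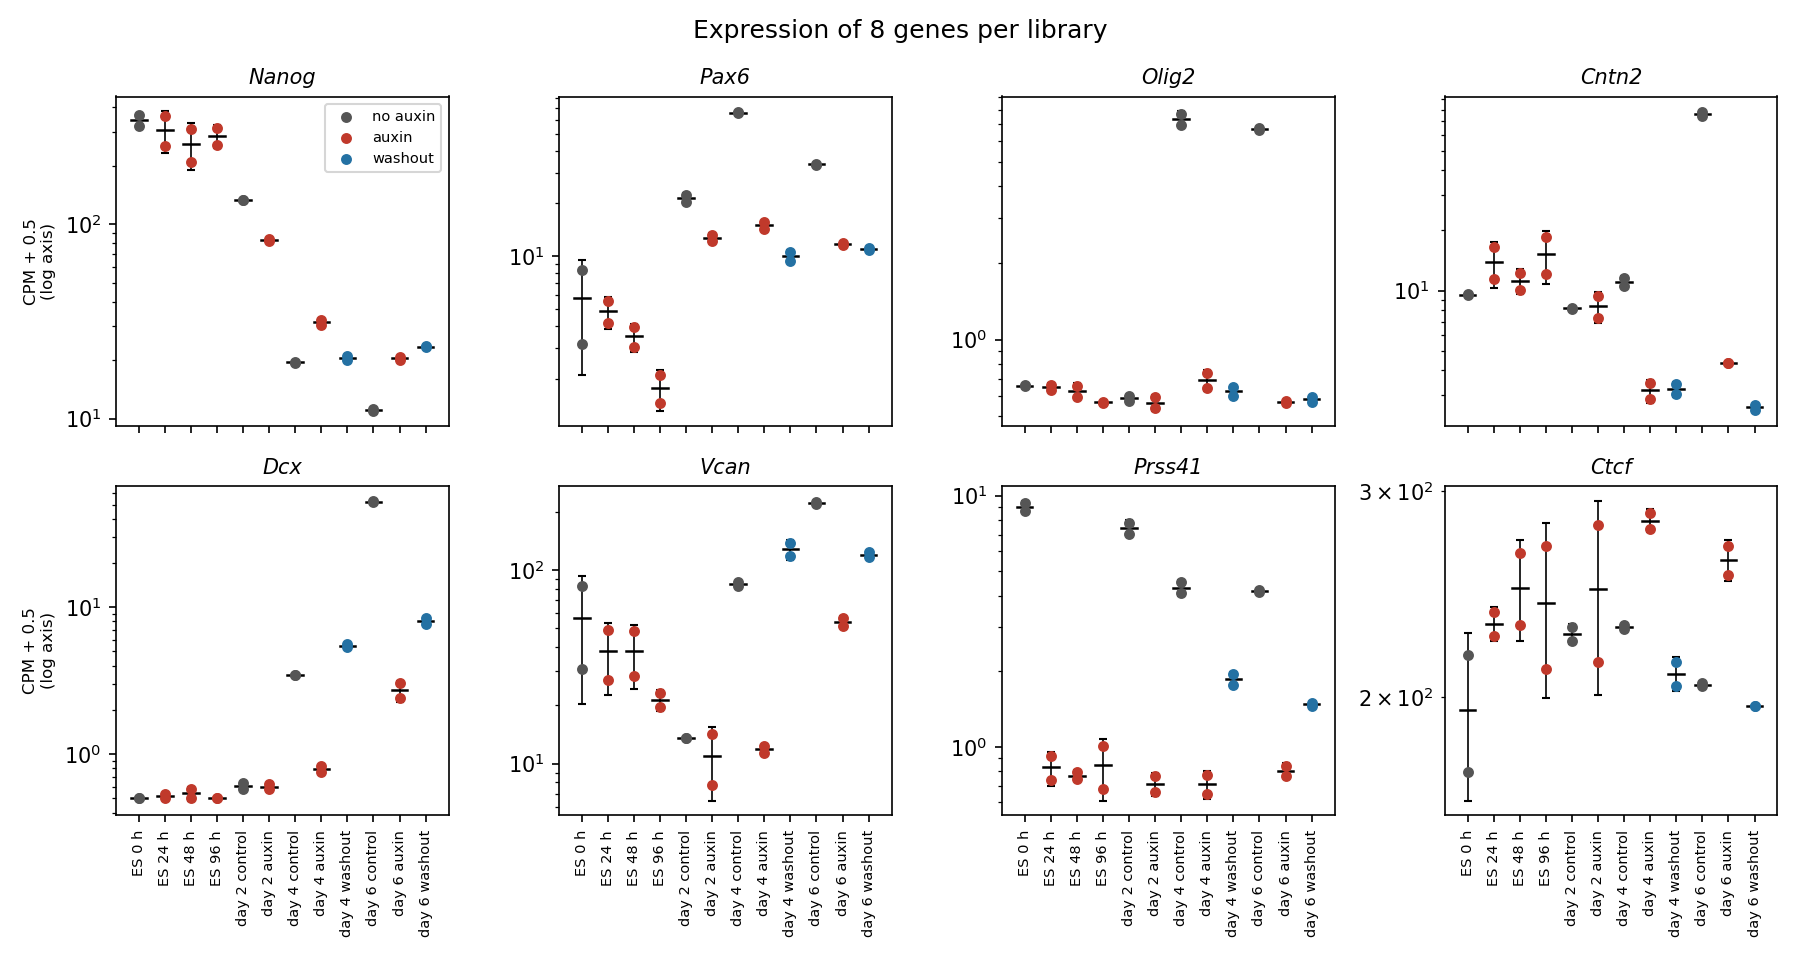
Scaled counts, CPM (log axis, 0.5 added) of Nanog, Pax6, Olig2, Cntn2, Dcx, Vcan, Prss41 and Ctcf in the 12 groups. Points are libraries (n = 2 per group), bars are means and whiskers are SD; with auxin Cntn2 is at 3.87 and 3.86 on day 6 against 74.3 and 77.3 in controls, and Ctcf stays at 172 to 287 in all libraries.

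The day 4 and day 6 changes overlapped. Genes higher on both days numbered 262, where 9.64 would be shared by chance, and genes lower on both numbered 362, where 17.1 would be. Fbxo15 was among the former, Olig2 and Cntn2 among the latter. Leaving out 1 library gave 71 (replicate 1 of the day 4 control) to 157 (replicate 2 of the day 6 auxin cells) and 169 (replicate 1 of the day 4 auxin cells) to 246. Of the genes higher after 96 h in ES cells, 146 were also higher on day 4 (14.4 by chance), Cpa1 among them, and 192 were lower in both (17.8 by chance), Prss41 among them. These were 42 and 94 without replicate 1 of the day 4 control, and 54 and 78 without replicate 1 of the day 4 auxin cells. The 48 h and 96 h comparisons in ES cells share their 0 h controls. They shared 321 higher genes (18.7 by chance) and 228 lower genes (10.9 by chance), C2cd4a and Prss41 among them, or 501 and 653 without replicate 1 of the 0 h cells. Simulated unchanged groups shared 72 to 101 and 49 to 61 under independent noise, and 0 to 1 and 0 to 3 with a shared replicate shift.

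Genes that differentiation moves were then followed under auxin, where most did not pass. Of 5240 genes higher in day 6 controls than in ES cells, 308 fell on day 4, Olig2, Cntn2 and Vcan among them, and 70 rose (median log2 fold change −0.07, camera p = 8.62e-05, and 0.0144 with an estimated correlation). Of 5185 genes that differentiation lowers, 144 rose, Fbxo15 among them, and 58 fell (median 0.08, camera p = 0.00117, and 0.00486 with an estimated correlation). On day 6, of 4733 genes higher by day 4, 412 fell, Olig2 and Nkx6-1 among them, and 209 rose (median −0.02, camera p = 0.021, and 0.107 with an estimated correlation), and of 4429 lower genes 243 rose and 118 fell (median 0.08, camera p = 0.0468, and 0.0477).

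Differences between auxin effects asked whether CTCF loss acts differently by stage. The day 4 effect differed from the 96 h ES effect in 294 genes, 184 of them lower in differentiation. Nkx6-1 (log2 fold change −5.31 ± 0.59, adjusted p = 0.00049), Rfx4 (−4.26 ± 0.49, adjusted p = 0.00049) and Cntn2 (−2.69 ± 0.32, adjusted p = 0.00049) were relatively lower on day 4, and Lefty2 was relatively higher (2.37 ± 0.36, adjusted p = 0.0034). Of 34 neural progenitor genes, 0 rose, 9 fell and 25 did not pass (0 higher and 11 lower, adjusted over the list alone) by this difference. The neural progenitor median was −1.04, set test adjusted p = 6.4e-10. The count of 294 was 654 and 514 without replicates 1 and 2 of the 0 h cells, 379 and 691 without those of the 96 h cells, 49 and 54 without those of the day 4 control, 58 and 53 without those of the day 4 auxin cells, and 0 with the compared groups alone. Between day 2 and day 6 the effect differed in 330 genes, 232 of them lower on day 6, among them Cntn2 (−4.33 ± 0.33, adjusted p = 2.7e-06), and Nkx6-1 (−5.82 ± 0.60, adjusted p = 7.5e-05) and Aldh1a2 (−4.06 ± 0.36, adjusted p = 2.2e-05), which rose on day 2, while Nanog (1.59 ± 0.24, adjusted p = 0.0014) and Esrrb (2.04 ± 0.33, adjusted p = 0.0024) were relatively higher. Of 30 neuronal genes, 0 rose, 17 fell and 13 did not pass (0 higher and 24 lower, adjusted over the list alone). Their median was −2.93, set test adjusted p = 5.7e-63. The count of 330 was 139 and 145 without replicates 1 and 2 of the day 2 control, 188 and 275 without those of the day 2 auxin cells, 162 and 158 without those of the day 6 control, 148 and 133 without those of the day 6 auxin cells, and 3437 in the 16 differentiation libraries alone. Between 48 h in ES cells and day 2, edgeR called 1 gene, against 8 and 4 without replicates 1 and 2 of the 0 h cells and 0 without replicate 1 of the 48 h cells, replicates 1 and 2 of the day 2 control or replicate 1 of the day 2 auxin cells, and DESeq2 called 35 genes.

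**Figure D4:**
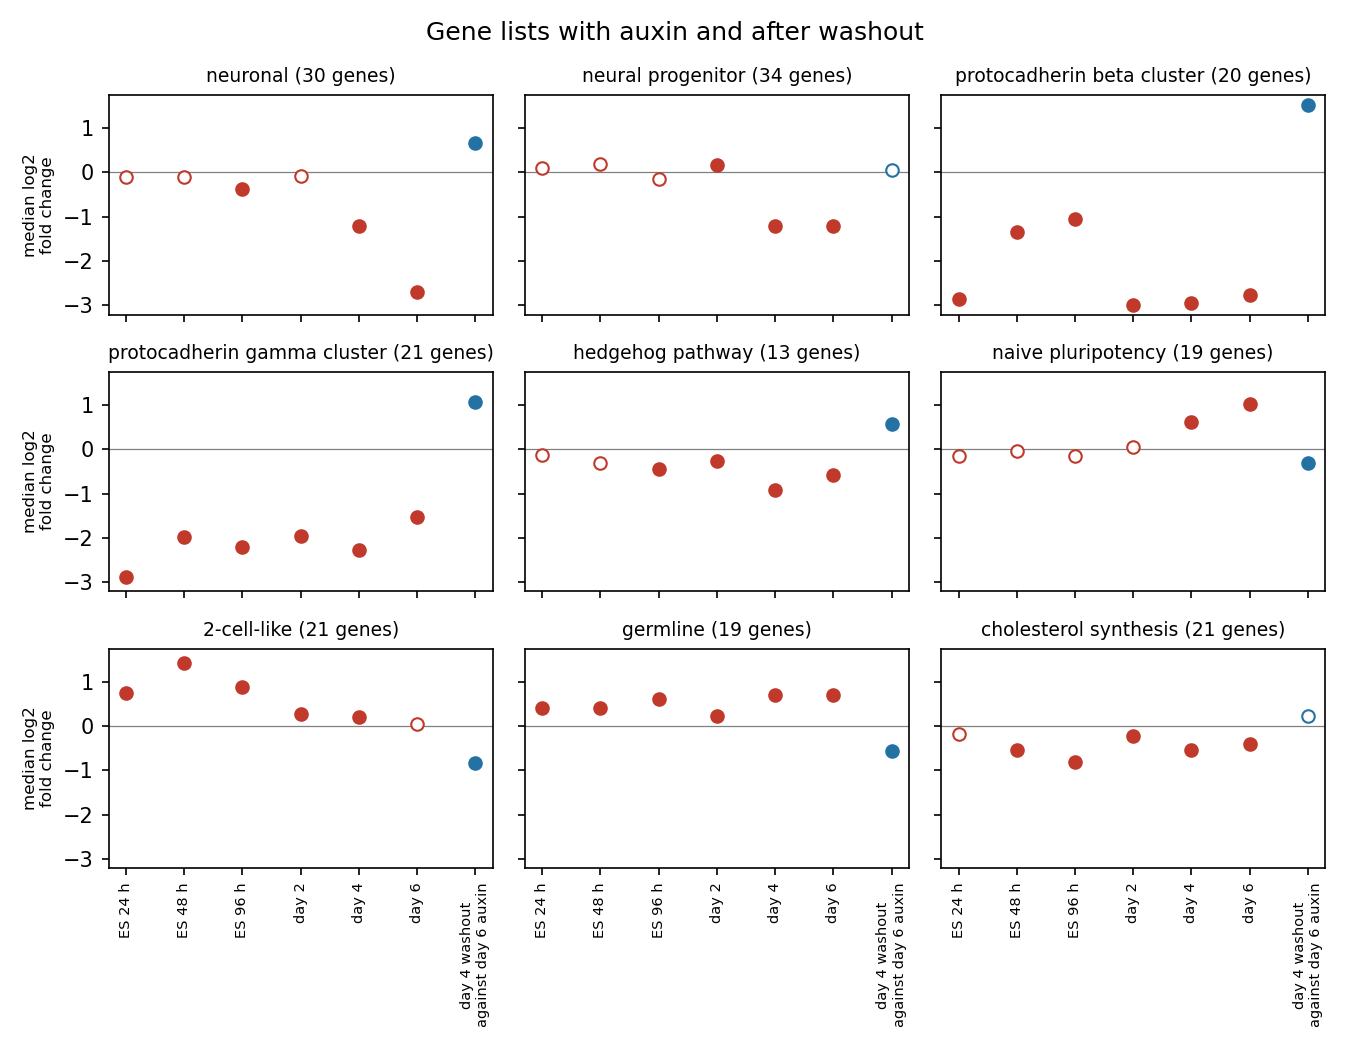
Median log2 fold change of 9 fixed gene lists in 7 comparisons: auxin in ES cells, auxin on days 2, 4 and 6, and day 4 washout against day 6 auxin. Filled points have a set test adjusted p below 0.05 and open points do not; the neuronal median is −1.2 on day 4, −2.69 on day 6 and 0.66 in washout, the last with adjusted p = 0.36 with an estimated correlation.

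Washout cells ask which changes reverse once auxin is removed. The day 4 washout cells were harvested on the day of the day 6 groups, so they were set against both. Against day 6 auxin cells, 764 genes were higher and 842 lower. The matrix gene Lum (log2 fold change 2.80 ± 0.45, adjusted p = 0.00093) rose, as did Gli1 (1.54 ± 0.19, adjusted p = 8.4e-05), Sox9 (1.23 ± 0.18, adjusted p = 0.00037), Isl1 (1.41 ± 0.24, adjusted p = 0.0013) and Peg12 (2.25 ± 0.33, adjusted p = 0.00037). Fbxo15 (−0.90 ± 0.12, adjusted p = 0.00015), Dppa3 (−1.59 ± 0.24, adjusted p = 0.00051), Grb10 (−1.23 ± 0.16, adjusted p = 0.00012), Cpa1 (−2.68 ± 0.44, adjusted p = 0.00093) and Zscan4b (−2.19 ± 0.29, adjusted p = 0.00013) fell. Of 21 protocadherin gamma genes, 7 rose, 0 fell and 14 did not pass (10 higher and 0 lower, adjusted over the list alone). Their median was 1.06, set test adjusted p = 2.4e-07 and adjusted p = 0.36 with an estimated correlation. Of 30 neuronal genes, 4 rose, 0 fell and 26 did not pass (8 higher and 1 lower, adjusted over the list alone). Their median was 0.66, set test adjusted p = 0.0016 and adjusted p = 0.36 with an estimated correlation. Vcan was higher (1.26 ± 0.36, adjusted p = 0.045), with adjusted p = 0.12 to 0.25 when any 1 of the 4 libraries was left out, at 128 ± 15 CPM (SD, n = 2) against 53.6 ± 3.7 with auxin and 222 ± 4.7 in controls. Tubb3 (0.45 ± 0.43, adjusted p = 0.65), Pax6 (−0.25 ± 0.32, adjusted p = 0.75) and Sox1 (−0.72 ± 0.46, adjusted p = 0.44) did not pass, but Tubb3 and Sox1 did in the 16 differentiation libraries alone (adjusted p = 0.002 and 0.0082). The count of 1606 was 587 and 556 without replicates 1 and 2 of the washout cells, 516 and 493 without replicates 1 and 2 of the auxin cells, and 7823 in the 16 differentiation libraries alone.

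Of the 319 genes higher with auxin on day 4, 149 (46.7%) were called lower in washout than in day 6 auxin cells and 3 higher, and of the 484 lower genes 163 (33.7%) were called higher and 3 lower. Together 312 of 803 (38.9%) moved back, Fbxo15, Gli1 and Peg12 among them. With 1 library left out, the 149 were 53 (replicate 1 of the day 4 control) to 117, and the 163 were 57 (replicate 2 of the day 6 auxin cells) to 137. Against day 6 controls, 71 (22.3%) and 158 (32.6%) were still called in their day 4 direction, Olig2 and Cntn2 among the latter. Median log2 changes of higher and lower genes were −0.84 and 0.68 against day 6 auxin cells, and 0.5 and −0.54 against controls. Auxin on day 6 gave 1.3 and −1.3, so the medians moved back in part.

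Against day 6 controls, day 4 washout cells had 727 genes higher and 908 lower. Cntn2 (−4.79 ± 0.26, adjusted p = 1.1e-08), Olig2 (−5.59 ± 0.37, adjusted p = 1.5e-07), Rfx4 (−4.67 ± 0.37, adjusted p = 8e-07), Elavl4 (−4.19 ± 0.40, adjusted p = 4.3e-06), Dcx (−3.38 ± 0.33, adjusted p = 1e-05), Sox1 (−3.31 ± 0.48, adjusted p = 0.00028), Pax6 (−1.80 ± 0.32, adjusted p = 0.0016) and Tubb3 (−3.15 ± 0.45, adjusted p = 0.00027) remained lower. Of 30 neuronal genes, 0 rose, 24 fell and 6 did not pass (0 higher and 26 lower, adjusted over the list alone). The neuronal median was −2.19, set test adjusted p = 5.7e-51. Of 34 neural progenitor genes, 0 rose, 17 fell and 17 did not pass (2 higher and 18 lower, adjusted over the list alone). The neural progenitor median was −1.24, set test adjusted p = 6e-18. Fbxo15 (0.71 ± 0.12, adjusted p = 0.001), Pou5f1 (0.90 ± 0.16, adjusted p = 0.0014) and Nanog (0.91 ± 0.17, adjusted p = 0.0023) were higher, and Vcan did not pass (−0.79 ± 0.36, adjusted p = 0.24, or 0.00092 in the 16 differentiation libraries alone). Egr4 (6.20 ± 0.85, adjusted p = 0.00017), Atf3 (3.26 ± 0.43, adjusted p = 0.00013) and Fosb (3.19 ± 0.47, adjusted p = 0.00036), transcription factor genes that respond quickly to stimuli, rose, Fosb also against day 6 auxin cells (4.39 ± 0.50, adjusted p = 3.4e-05), while Mir6236, annotated as a microRNA (−2.77 ± 0.21, adjusted p = 1.1e-06), and the structured RNAs Rn7sk (−3.04 ± 0.55, adjusted p = 0.0023, but adjusted p = 0.066 without replicate 1 of the day 4 washout cells) and Rpph1 (−2.97 ± 0.41, adjusted p = 0.00022) were lower than in those cells, and the pseudogenes Eif5al3-ps (3.80 ± 0.41, adjusted p = 1.9e-05) and Rpl36-ps3 (3.42 ± 0.40, adjusted p = 3.7e-05) higher. The 4 washout libraries stood apart from the rest in the share of even values among low counts, at 59.6% to 60.5% against 65.9% to 78%. The count of 1635 was 661 and 621 without replicates 1 and 2 of the washout cells, 622 and 656 without replicates 1 and 2 of the control, and 7658 in the 16 differentiation libraries alone.

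Day 6 washout cells were harvested 2 days later than any other group, so the day of harvest differs in their comparisons. Against day 6 auxin cells 1155 genes were higher and 1182 lower. Matrix and fibroblast genes rose: Col6a3 (log2 fold change 4.18 ± 0.45, adjusted p = 1.2e-05), Col6a1 (3.28 ± 0.27, adjusted p = 8.4e-07), and Sparcl1 (4.47 ± 0.45, adjusted p = 6.3e-06). Fosb rose as well (4.97 ± 0.52, adjusted p = 8.5e-06). Of 19 fibroblast or feeder genes, 14 rose, 0 fell and 5 did not pass (17 higher and 0 lower, adjusted over the list alone). The fibroblast median was 2.00, set test adjusted p = 7.6e-25. Of 21 protocadherin gamma genes, 8 rose, 0 fell and 13 did not pass (12 higher and 0 lower, adjusted over the list alone). The protocadherin gamma median was 1.57, set test adjusted p = 1.1e-07 and adjusted p = 0.48 with an estimated correlation. Fbxo15 (−1.16 ± 0.12, adjusted p = 8.2e-06) and Mir6236 (−3.11 ± 0.22, adjusted p = 2.9e-07) fell, and Vcan did not pass (1.16 ± 0.36, adjusted p = 0.05, or 2e-05 in the 16 differentiation libraries alone). Against day 6 controls, where 1166 were higher and 1189 lower, Cntn2 (−5.16 ± 0.26, adjusted p = 4.2e-09), Olig2 (−6.18 ± 0.39, adjusted p = 8.4e-08), Sox1 (−3.87 ± 0.49, adjusted p = 4.8e-05) and Tubb3 (−2.43 ± 0.44, adjusted p = 0.0013) were lower. There 0 rose, 26 fell and 4 did not pass (0 higher and 28 lower, adjusted over the list alone) of 30 neuronal genes. The neuronal median was −2.32, set test adjusted p = 2.6e-46. The smooth-muscle genes Mylk (3.91 ± 0.35, adjusted p = 1.6e-06) and Tagln (4.12 ± 0.62, adjusted p = 0.00026) and the pluripotency gene Nanog (1.11 ± 0.17, adjusted p = 0.00033) were higher. The counts of 2337 against auxin cells and 2355 against controls were 942 and 954 without replicate 1 of the washout cells and 903 and 1028 without replicate 2. They were 945 and 840 without replicates 1 and 2 of the day 6 auxin cells and 979 and 998 without those of the control.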

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

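Of the tests below, those on glycolysis genes, the washout libraries and neuronal genes were chosen after the result was seen, and the differences between auxin effects before. Auxin effects differed by a direct test of the difference in 294 genes for day 4 minus 96 h in ES cells (0 with the compared groups alone), 330 for day 6 minus day 2 and 1 for day 2 minus 48 h, and 349 genes differed between 96 h and 24 h of auxin in ES cells. In the day 4 minus 96 h difference Nkx6-1 had a log2 value of −5.31, Rfx4 −4.26, Cntn2 −2.69 and Lefty2 2.37, and the neural progenitor list had a median of −1.04. In the day 6 minus day 2 difference Nkx6-1 had −5.82, Cntn2 −4.33, Aldh1a2 −4.06, Nanog 1.59 and Esrrb 2.04, and the neuronal list had a median of −2.93. At 96 h against 24 h, where the 8 ES libraries with a replicate block called 3 genes, Tdgf1 had −1.21, Havcr1 1.91 (block adjusted p = 0.13) and Lefty2 −1.73 (block adjusted p = 0.092), and the cholesterol synthesis and glycolysis lists had medians of −0.61 and −1.22 (adjusted p = 0.058 and 0.18 with an estimated correlation).

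Glycolysis and hypoxia genes were lower in ES cells after 96 h of auxin than at 0 h. Between the replicate 1 libraries the median log2 ratio of the 21 members was 0.09, with 10 of 21 lower, between the replicate 2 libraries it was −1.77, with 21 of 21 lower, and at 0 h replicate 2 was above replicate 1 by a median of 1.82. The fall of the list from 0 h may therefore come from replicate 2 of the 0 h cells, although Slc2a1 (552 to 227 CPM) and Eno1 (737 to 388 CPM) were lower between the replicate 1 libraries too. From 24 h to 96 h the median was −0.6 (bootstrap interval −0.71 to −0.33) between the replicate 1 libraries, with 19 of 21 lower, and −1.63 between those of replicate 2, but with 1 library per time and a larger difference between the 0 h replicates, replicate 2 of the 24 h cells, auxin and time in culture stay open. A loss of CTCF that lowers these genes in any cell state is excluded as the whole cause, since the day 4 median was 0.05 (bootstrap interval −0.15 to 0.1).

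The washout libraries stood apart from the rest in a feature of their low counts. In 4 of 4, the share of even values among low counts (59.6% to 60.5%) lay outside that of the other 20 libraries (65.9% to 78%), so a difference in library or read processing may add to changes such as the rise of Fosb and of the pseudogenes Eif5al3-ps and Rpl36-ps3 and the fall of Mir6236, Rn7sk and Rpph1. A shift shared by the washout libraries that is alike for genes of like expression is excluded as the whole cause of the move back. This holds for the day 4 genes as a set, not for single genes such as Fbxo15 and Gli1. The random sets used were matched for expression alone, so a washout shift along differentiation is not excluded. Genes higher and genes lower with auxin on day 4 moved apart by −1.52 on the log2 scale from day 6 auxin to washout cells, where 10000 random sets gave −0.13 to 0.12. Whether processing differed, and changed genes in any washout comparison, stays open, since both washout groups share both features.

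Neuronal genes fell and naive pluripotency genes rose with auxin on day 6, which might come from ES cells left in the cultures or from slower differentiation. Over 19 neuronal members a median of 15.8% of the control level remained (bootstrap interval 5.09% to 21.5%), while 12 naive members gave an ES share of 7.85% by median and 47.5% at most, for Fbxo15. A mixture of normal neural cells with that share of ES cells is thus excluded as the whole cause of the fall. So is a delay of up to 2 days. With auxin on day 6, neuronal members were below day 4 controls by a median of −0.52 (bootstrap interval over genes −1.27 to −0.3), lower in 15 of 19 and higher in 4. A longer delay, an effect of CTCF loss on neuronal genes or of auxin itself, or a change to other cell types remain open and were not tested.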

How the results depend on the processing

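The alternatives in this part that use the 8 ES, the 16 differentiation or the 12 differentiation libraries without washout alone, and that halve the counts, were added after seeing the data. The other alternatives, the comparisons and the lists were chosen before the data were examined. Of 234 values of named genes, 233 kept their direction in the alternatives run for them and 160 also kept their side of the threshold. Of 54 values of lists, 54 kept their direction in those run for lists and 30 also their side. The exception was Vcan at 24 h in ES cells, at 0.29 and −1.13 without replicate 1 or 2 of the 0 h cells against −0.59 ± 0.36. The cause was not tested for any change below, except that a stricter threshold calls fewer genes by construction. A 2-fold change on day 4 was found for 32% of 97 simulated genes in the fit of 24 libraries and for 63.8% of 94 in the 16 differentiation libraries.

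At an adjusted p below 0.01 the count of genes was 154 for 24 h of auxin in ES cells, 288 for 48 h, 802 for 96 h and 44 for 96 h against 24 h. It was 2185 for day 2 control against ES cells and 154, 420 and 876 for auxin on days 2, 4 and 6. Against auxin and control, day 4 washout gave 706 and 795 and day 6 washout 1142 and 1192. Genes higher and lower in both were 65 and 80 for 96 h and day 4, 115 and 214 for day 4 and day 6, and 112 and 98 for 48 h and 96 h. Day 4 higher and lower genes that moved back were 56 and 85. The differences held 51 for day 4 minus 96 h, 144 for day 6 minus day 2 and 0 for day 2 minus 48 h. Beside the 0, edgeR gave 1113 genes at an unadjusted p under 0.05 for that difference and DESeq2 called 35. With a log2 change of at least 1 the count was 1172 for 96 h, 210 for 96 h against 24 h, 2618 for day 2 control against ES cells, 6030 for day 4 control, 90 for day 4 higher genes that moved back, 92 for genes higher in both 96 h and day 4, 108 for genes lower in both 96 h and day 4, 213 for genes higher in both 48 h and 96 h and 124 for genes lower in both 48 h and 96 h. Without a filter on low counts it was 1152 for 48 h, 908 for 96 h against 24 h, 532 for auxin on day 2, 70 for the day 2 minus 48 h difference, 777 for the day 4 minus 96 h difference, 562 for the day 6 minus day 2 difference, 483 for genes higher in both 48 h and 96 h and 378 for genes lower in both 48 h and 96 h. The day 2 minus 48 h difference held 2 genes with relative log expression scaling, 4 with a mean of at least 1 CPM and 2 with counts halved. DESeq2 called 627 for 24 h of auxin in ES cells, 1452 for 48 h, 3000 for 96 h, 1041 for 96 h against 24 h, 797 for auxin on day 2, 1446 for auxin on day 4, 2488 for day 4 washout against auxin, 2518 for day 4 washout against control, 35 for the day 2 minus 48 h difference, 871 for the day 4 minus 96 h difference and 711 for the day 6 minus day 2 difference. With an estimated correlation, 57 of 248 list calls passed.

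Counts also moved with the set of libraries fitted. With the compared groups alone the count was 0 for each of 24 h, 48 h, 96 h and 96 h against 24 h in ES cells. It was 238, 4419 and 5945 for controls on days 2, 4 and 6 against ES cells, and 882, 7864 and 8976 for auxin on those days. Against auxin and control, day 4 washout gave 9185 and 9088 and day 6 washout 11589 and 10768. The differences held 0 for day 2 minus 48 h, 0 for day 4 minus 96 h and 2130 for day 6 minus day 2. The 8 ES libraries alone gave 0 for each of 24 h, 48 h, 96 h and 96 h against 24 h in edgeR, where all libraries gave 2179 and 3562 genes at an unadjusted p under 0.05 for 24 h and 48 h, and with a replicate block 23 for 24 h of auxin in ES cells, 40 for 48 h, 621 for 96 h and 3 for 96 h against 24 h. The 16 differentiation libraries alone gave 4126, 5318 and 6588 for auxin on days 2, 4 and 6 and 3437 for the day 6 minus day 2 difference. Against auxin and control they gave 7823 and 7658 for day 4 washout and 9097 and 8333 for day 6 washout. The 12 without washout gave 3610, 4835 and 6095 for auxin on days 2, 4 and 6 and 2987 for that difference.

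The median log2 fold change of genes lower by day 4, under auxin on day 6, was 0.08 and passed its test; it was 0.06 with relative log expression scaling or counts halved and 0.04 with a mean of at least 1 CPM, and did not pass there. That of genes higher by day 4 was −0.01 under the last and did not pass.

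Leaving out 1 library at a time gave counts of 225 to 1220 for 24 h of auxin in ES cells, 453 to 1656 for 48 h, 1504 to 2659 for 96 h, 1932 to 6051 for day 2 control against ES cells, 6199 to 9007 for day 4 control, 7656 to 10299 for day 6 control, 0 to 8 for the day 2 minus 48 h difference, 49 to 691 for the day 4 minus 96 h difference, 42 to 216 for genes higher in both 96 h and day 4, 78 to 213 for genes lower in both 96 h and day 4, 225 to 501 for genes higher in both 48 h and 96 h, 142 to 653 for genes lower in both 48 h and 96 h, 53 to 640 for 96 h against 24 h, 105 to 228 for auxin on day 2, 133 to 275 for the day 6 minus day 2 difference, 290 to 325 for auxin on day 4, 53 to 117 for day 4 higher genes that moved back, 57 to 137 for day 4 lower genes that moved back, 71 to 157 for genes higher in both day 4 and day 6, 169 to 246 for genes lower in both day 4 and day 6, 493 to 587 for day 4 washout against auxin, 621 to 661 for day 4 washout against control, 682 to 723 for auxin on day 6, 954 to 1028 for day 6 washout against control and 840 to 945 for day 6 washout against auxin. The medians were −0.09 to −0.04 and 0.06 to 0.13 for genes higher and lower by day 6 under auxin on day 4. They were −0.04 to −0.02 and 0.05 to 0.1 for genes higher and lower by day 4 under auxin on day 6. Day 4 higher and lower genes in washout gave −1.19 to −0.8 and 0.72 to 1.02, against −0.84 and 0.68 with all libraries.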

Other observations

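Of the tests below, the neighbour counts outside day 6 and the measures of day 6 change in early genes were chosen after the result was seen, and the tests of the 2 hypotheses before. Values of further fixed lists follow. Of 14 neural crest genes, 1 rose, 4 fell and 9 did not pass (2 higher and 5 lower, adjusted over the list alone) with auxin on day 6. The neural crest median was −0.27, set test adjusted p = 0.00036 and adjusted p = 0.15 with an estimated correlation. Tfap2b (−6.46 ± 0.85, adjusted p = 0.00016) fell there, as did Sox9 (−0.99 ± 0.18, adjusted p = 0.0018). Among 36 imprinted genes, which are expressed from the chromosome of 1 parent, 1 rose, 3 fell and 32 did not pass (1 higher and 7 lower, adjusted over the list alone) on day 4. The imprinted median was −0.21, set test adjusted p = 0.00097 and adjusted p = 0.18 with an estimated correlation. The members moved both ways: Grb10 rose on day 4 (1.48 ± 0.16, adjusted p = 3e-05) and day 6 (2.23 ± 0.17, adjusted p = 4.5e-07), and Plagl1 (−2.19 ± 0.23, adjusted p = 2.2e-05) and Peg12 (−2.56 ± 0.33, adjusted p = 0.00013) fell on day 4. In washout cells Grb10 fell (−1.23 ± 0.16, adjusted p = 0.00012) and Peg12 rose (2.25 ± 0.33, adjusted p = 0.00037) against day 6 auxin cells.

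Genes of the 2-cell-like state, higher in ES cells after 48 h of auxin, were lower in day 6 controls than in ES cells: of 21, 0 rose, 19 fell and 2 did not pass (0 higher and 19 lower, adjusted over the list alone). The 2-cell-like median was −2.11, set test adjusted p = 4.2e-11 and adjusted p = 0.055 with an estimated correlation. Sp110 (−4.17 ± 0.37, adjusted p = 7.5e-08), Zscan4a (−2.46 ± 0.25, adjusted p = 3.3e-07) and Tcstv3 (−3.49 ± 0.37, adjusted p = 7e-07) fell. Day 4 washout cells were below day 6 auxin cells in this list, where 0 rose, 7 fell and 14 did not pass (0 higher and 8 lower, adjusted over the list alone). The 2-cell-like median was −0.83, or −0.82 with members at 0 in 1 group set at their bound, set test adjusted p = 7.1e-08 and adjusted p = 0.25 with an estimated correlation. Zscan4a fell (−1.81 ± 0.26, adjusted p = 0.00031).

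A hypothesis was that CTCF loss moves neighbouring genes together. On day 6, 134 pairs of adjacent, non-overlapping tested genes were called in the same direction, among them Gsdma2 and Gsdma, and Pantr1 and Pou3f3, named here after their values were seen. Shuffles of the calls among genes of like expression gave a median of 44 and at most 71 (10000 shuffles, permutation p = 1e-04, the smallest they can give). Pairs called in opposite directions numbered 30 against a median of 43, and pairs whose symbols differ in their first 3 letters numbered 101 against 40, so gene families do not account for all of the excess. Changes may thus extend over neighbouring genes, but differentiation showed such pairs as well: 2670 against 1850 from ES cells to day 6 controls, a ratio of 1.44, against 3.05 for auxin on day 6, 3.92 on day 4 and 2.07 for 96 h in ES cells. On day 2 there were 4 pairs against a median of 2, where shuffles reached 9. Whether those ratios differ was not tested.

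A further hypothesis was that genes changed early, on day 2 as well as day 4, move back further after washout. In the 188 genes called on both days a median share of 0.67 of the day 4 change was reversed from day 6 auxin to washout cells. It was 0.46 in the 615 called on day 4 but not on day 2. The difference was 0.21 (two-sided permutation p = 1e-05, the smallest that 1e+05 permutations can give, with genes taken as independent). Calls on day 2 depend on the fit, so some of the 615 may have changed by then. Of the 188 and 615, 117 and 195 genes were called opposite to their day 4 change. The early genes kept a median of 0.87 of their day 4 change on day 6, against 0.96, and their move back was 0.74 of the day 6 change, against 0.53. They may respond more directly to CTCF, which was not tested.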
